A study of Mytilus galloprovincialis with 24 samples.

How the data were processed

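The series holds 24 Agilent arrays of mussel digestive gland RNA, each from a pool of 3 glands, in 6 groups of 4 (control or 2.5 µg/L ketoprofen for 14, 30 or 60 days), as the labels give them. Groups and replicate numbers were taken from the sample titles. RNA was amplified and labelled with cyanine 3 by a low-input one-colour protocol, per the labels. The series title also names diclofenac and ibuprofen, for which no sample is present. The deposited intensity values come from Agilent Feature Extraction 10.1.1.1 on scanner G2505C at 3 microns with the extended dynamic range on, per the file headers, whereas the series design names Feature Extraction 10.7.3.1 and scanner G2565BA at 2 microns. The processed signal used here is the background-subtracted, multiplicatively detrended intensity with dim spots replaced by a surrogate value, per the file headers, and is not normalized between arrays. The well-above-background, saturation and outlier flags are also those of Feature Extraction, per the file headers. The deposited series matrix holds linear intensity values of the same arrays: each column had the same ranks as that array's processed signal (Spearman's rho of 1), a median of 30.8 and the same maximum in all columns, as after quantile normalization. The step behind it is not given in the sources used here.

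The main values were log2 of the processed signal minus each array's 75th percentile over the 59971 probes that are not control spots. The 398 spots with an outlier flag were set missing and saturated spots, 13 in all, were kept. The 40687 probes, or 67.8%, well above background on at least 3 of 4 arrays of at least 1 group were tested. One model with a mean per group was fitted over all 24 arrays (lmFit and eBayes of limma 3.58.1 in R 4.3.3, 18 residual degrees of freedom, 2.30 prior degrees of freedom), and p was adjusted by the method of Benjamini and Hochberg, with calls at an adjusted p under 0.05, two-sided. The contrasts were ketoprofen minus control at each time, the mean of the 3 differences, an F-test of the 2 interaction contrasts, and an F-test over the 3 control groups with its pairwise contrasts. These tests, the filter, the alternatives and the rule for named probes were set before the data were examined, except where the text says otherwise.

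A probe not well above background on any array of a group has only a bound there. Its ratio is written as "at least N-fold": the brighter group's mean against the mean, per array of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background. Such bounds hold for the processed signal only. Values after normexp background correction, which adds an offset to all signals, are estimates on that scale and can lie under them. No gene could be named: all probe descriptions in the files are "Unknown", and 0 of the probe names were found among the 43856 genes of the RefSeq table (assembly xbMytGall1.hap1.1). The 28 gene lists fixed beforehand, among them arachidonic acid metabolism, xenobiotic metabolism and immune genes, rest on names or descriptions and were not applied. The rule for named probes without gene names was the 2 probes of smallest p with higher and the 2 with lower values per contrast. For the interaction the direction was that of the 60-day minus the 14-day effect, and for control time that of 60 against 14 days.

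Exact permutation tests over all probes without missing values used the 35 splits of the 8 arrays of a time into 4 and 4, with the root mean square of the mean log2 differences or the mean distance to the group mean as the statistic, and the correlation of the differences at 2 times used all splits of both times. Correlations across arrays have p-values from 100000 permutations. Slides were read from the array barcodes (3 slides of 8 arrays, each holding several groups) and the 2 scan days from the headers, with slide 1 scanned on the first day and slides 2 and 3 on the second. The counts were recomputed with quantile normalization, median centring, normexp background correction with an offset of 50, the series matrix, no filter, only the 24598 probes well above background on all arrays, a mean-variance trend with robust eBayes, array weights, the replicate number within each time (which cannot estimate control time), slide or scan date as a block, a threshold that adds a 1.5-fold change, and leaving out each array in turn. The counts at a single time were also recomputed from the 8 arrays of that time alone.

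The procedure was tested on simulated data with each probe's real spread and 50 probes changed at each of 4 sizes among 40687. The noise was normal, independent between probes and equal in all groups, unlike the real data. The counts that follow may therefore not carry over. For the 14-day contrast it called 2 of 50 probes changed 2-fold, 20 changed 4-fold, 36 changed 8-fold and 35 changed 16-fold, with 4 unchanged probes called. For the average over times it called 19, 36, 45 and 46 of 50, with 13 unchanged probes called. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.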

Results

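RNA from the digestive gland of the Mediterranean mussel, Mytilus galloprovincialis, was measured on 24 single-colour arrays. The digestive gland is the organ in which the mussel digests its food and in which much of what it takes up from water is metabolised. Mussels were kept in seawater with 2.5 µg/L of ketoprofen, a nonsteroidal anti-inflammatory drug that inhibits cyclooxygenases in vertebrates, or in seawater with the methanol carrier alone. Glands were sampled after 14, 30 and 60 days, which gave 6 groups of 4 arrays. Each array carried a pool of 3 glands, so that n counts pools. The 6 groups are named CTRL_14d, KET_14d, CTRL_30d, KET_30d, CTRL_60d and KET_60d. The labels do not say which aquarium an array's animals came from, so a tank effect cannot be separated from the drug.

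The array held 59971 mussel probes of 60 bases, of which 40687 were well above background on at least 3 of the 4 arrays of at least 1 group and were tested. The signal at the 75th percentile of an array ranged from 72.3 to 290.2. Between 55.3% and 70% of the probes of an array were well above background. Pools of 1 group correlated with each other at a mean r of 0.942 in CTRL_14d and 0.894 in KET_60d, the highest and lowest of the 6 groups, across 24398 probes. The files name each probe by a contig identifier and describe every probe as unknown, and none of the identifiers appears in the gene table of the mussel genome. Results are therefore given by probe identifier and, for the leading probes, by the 60 bases of the probe.

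The first question was whether 14 days in ketoprofen changed transcript levels. No probe passed limma's test at an adjusted p under 0.05. At an unadjusted p under 0.05, 2411 passed, where uniform p would give 2034. Other splits of the same 8 arrays into 4 and 4 gave a median of 1312. The lowest adjusted p, 0.0825, belonged to ALL2_C68606_P (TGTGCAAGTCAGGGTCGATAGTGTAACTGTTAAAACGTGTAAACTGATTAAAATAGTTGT). Its mean log2 level relative to the array's 75th percentile was -0.58 ± 0.66 (SD, n = 4) in CTRL_14d and -5.31 ± 1.53 in KET_14d, a log2 difference of -4.73 with a standard error of 0.72. It was well above background on 4 of 4 control arrays and 1 of 4 ketoprofen arrays. At 30 and 60 days the difference for this probe was 1.1 and -0.70, each with a standard error of 0.72. ALL2_REP_C16136_P was not well above background on any KET_14d array and was at least 1.7-fold brighter in CTRL_14d by the processed signal (adjusted p = 0.386), and 1.35-fold with normexp (log2 -0.43). Among probes with higher values in KET_14d, ALL2_C98077_P had a log2 difference of 1.81 ± 0.41 (SE, adjusted p = 0.471) and ALL2_C72035_P of 1.51 ± 0.34 (adjusted p = 0.487). Both were well above background on 2 of 4 CTRL_14d arrays, and with normexp their differences were 0.22 and 0.16. For 1517 probes, or 3.73% of those tested, the 4 ketoprofen pools all lay on one side of the 4 control pools, where chance gives 2.86%. The call for ALL2_C68606_P depended on the processing and on single arrays. It passed after quantile normalization, in the deposited series matrix and with array weights, and not after median centring. It also passed on leaving out KET_14d array 3, KET_60d array 3 or KET_60d array 4. Over the 24 fits that leave out 1 array its adjusted p ranged from 0.00852 to 0.517. With normexp background correction, which adds an offset of 50 to all signals, its difference was -1.35 (adjusted p = 0.999) and 784 probes passed an unadjusted p under 0.05. Without KET_14d array 3 the count of called probes was 5, and without CTRL_14d array 3 ALL2_REP_C16136_P was called (adjusted p = 0.0245).

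After 30 days no probe passed limma's test either. The smallest adjusted p was 1, and 1346 probes passed an unadjusted p under 0.05, fewer than the 2034 that uniform p would give. Other splits of those 8 arrays gave a median of 1848. The smallest unadjusted p among probes with higher values in KET_30d belonged to ALL2_REP_C26392_S, at a mean log2 level of -4.84 ± 1.67 (SD, n = 4) in CTRL_30d and -1.51 ± 0.46 in KET_30d. It was well above background on 2 of 4 CTRL_30d arrays. ALL2_REP_C17306_P was not well above background on any of the 4 CTRL_30d arrays and was well above it on all 4 KET_30d arrays. It was at least 29.7-fold brighter in KET_30d by the processed signal and 5.17-fold with normexp (log2 2.37). By the processed signal it was also at least 15.4-fold brighter in CTRL_14d, and at least 32.9-fold in CTRL_60d, than in CTRL_30d. In KET_60d the same probe was well above background on 2 of 4 arrays, against 4 of 4 in CTRL_60d. ALL2_REP_C41360_P and ALL2_C71646_P had the smallest p among probes with lower values in KET_30d, with log2 differences of -2.07 ± 0.45 and -1.78 ± 0.40 (SE). ALL2_C71646_P was well above background on 1 of 4 KET_30d arrays, so its difference rests on signals near background. The 4 pools of each group did not overlap for 785 probes, or 1.93%, where chance gives 2.86%. Without CTRL_30d array 3 ALL2_REP_C26392_S was called (adjusted p = 0.0047), and over the 24 fits that leave out 1 array its adjusted p reached 1. With normexp its log2 difference was 0.94, against 3.33, and those of ALL2_REP_C41360_P and ALL2_C71646_P were -1.13 and -0.26.

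After 60 days the count of called probes was again 0. At an unadjusted p under 0.05 there were 2270, where other splits of the 8 arrays gave a median of 2444. The lowest adjusted p was 0.218 by limma. That value belonged to ALL2_C85538_P, which was well above background on 4 of 4 CTRL_60d arrays and on no KET_60d array, at least 2.40-fold brighter in the controls. ALL2_C8587_P had the same pattern of detection at 60 days and was at least 2.02-fold brighter in CTRL_60d (adjusted p = 0.463). It was not well above background on any CTRL_14d or CTRL_30d array either, and was at least 1.92-fold brighter in CTRL_60d than in CTRL_30d. ALL2_REP_C40510_P had a mean log2 level of -4.23 ± 2.01 (SD, n = 4) in CTRL_60d and -0.46 ± 0.24 in KET_60d (adjusted p = 0.372). It was well above background on 2 of 4 CTRL_60d arrays, so the control mean rests partly on signals near background. ALL2_REP_C26344_AS was well above background on all 4 KET_60d arrays and on no array of the other 5 groups, at least 1.45-fold brighter than in CTRL_60d (adjusted p = 0.463). The pools did not overlap for 977 probes, or 2.40%, where chance gives 2.86%. ALL2_C85538_P was called on leaving out KET_30d array 4 (adjusted p = 0.0053) or KET_30d array 1, arrays of another time that enter this contrast only through the shared spread, and its adjusted p reached 0.502 on leaving out CTRL_60d array 4. ALL2_C8587_P was called without KET_14d array 1 (adjusted p = 0.0293) and ALL2_REP_C40510_P without CTRL_60d array 4 (adjusted p = 0.0115). With normexp the log2 difference was -0.61 for ALL2_C85538_P, -0.49 for ALL2_C8587_P, 1.31 for ALL2_REP_C40510_P and 0.09 for ALL2_REP_C26344_AS.

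**Figure D1:**
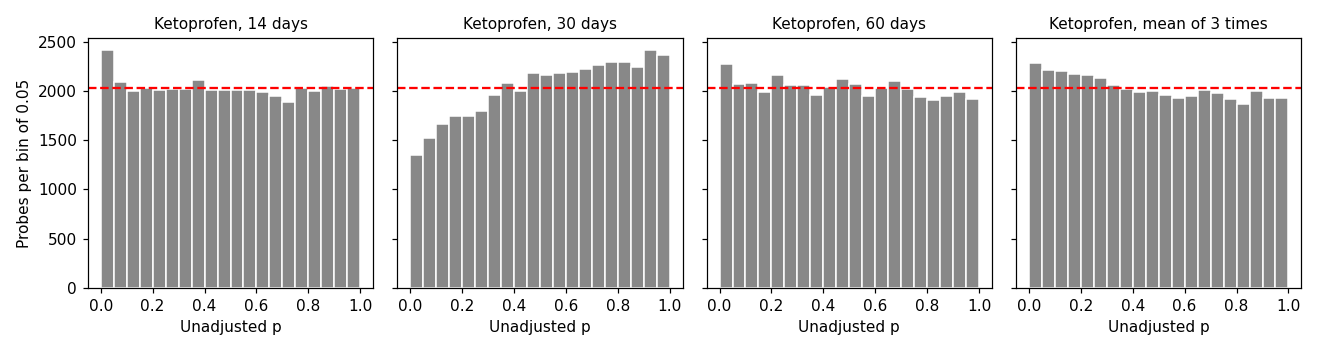
Number of probes per bin of unadjusted p (horizontal axis, bins of 0.05) for ketoprofen minus control at 14, 30 and 60 days and on average over the 3 times. The dashed line is the 2034 probes per bin that uniform p would give. The lowest bin holds 2411, 1346, 2270 and 2280 probes.

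A response shared by the 3 times was tested on the mean of the 3 differences, with 12 pools in each arm. By limma's test 1 probe passed, ALL2_C12067_P (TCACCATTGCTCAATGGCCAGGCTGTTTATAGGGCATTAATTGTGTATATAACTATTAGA), whose average log2 difference was -3.85 with a standard error of 0.55, a 14.4-fold lower level with ketoprofen (adjusted p = 0.0288). The log2 difference was -3.97 at 14 days, -3.50 at 30 days and -4.07 at 60 days, each with a standard error of 0.95. Its mean log2 level was 0.08 ± 0.60 (SD, n = 4) in CTRL_14d, 1.53 ± 0.53 in CTRL_30d and 1.23 ± 1.82 in CTRL_60d, and -3.89 ± 2.20, -1.97 ± 1.62 and -2.85 ± 0.65 in the ketoprofen groups of the same times. At each time the 4 ketoprofen pools lay below all 4 control pools. With normexp the difference was -2.23, a 4.69-fold lower level (adjusted p = 0.00729). With the replicate number as a block the difference stayed at -3.85 and the call ended (adjusted p = 0.314), and with slide as a block the difference was -4.05 ± 0.53 (SE). Over the alternatives other than leaving out 1 array the adjusted p ranged from 0.00729 to 0.314. Within slides the difference at 14 days was -2.86 on slide 1 and -6.83 on slide 2. At 30 days it was -3.06 on slide 1, and at 60 days -1.22 on slide 2 and -5.13 on slide 3. These values come from 1 to 3 arrays per group. The value of -6.83 rests on KET_14d array 1 alone, the only array on which the probe was not well above background (-7.05). On leaving out 1 array the difference ranged from -4.15 to -3.50 and the adjusted p from 0.00278 to 0.0946. The call ended in 14 of these 24 fits: without CTRL_14d array 1, 3 or 4, KET_14d array 3, any of the 4 CTRL_30d arrays, KET_30d array 3, CTRL_60d array 2 or 4, or KET_60d array 1, 2 or 4.

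The probes next in rank had lower values with ketoprofen as well and did not pass. ALL2_REP_C98839_S (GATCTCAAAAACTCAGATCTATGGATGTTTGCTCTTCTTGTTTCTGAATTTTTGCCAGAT) had an average log2 difference of -2.66 ± 0.42 (SE, adjusted p = 0.0506), and of -1.78 with normexp (adjusted p = 0.172). ALL2_C53135_S (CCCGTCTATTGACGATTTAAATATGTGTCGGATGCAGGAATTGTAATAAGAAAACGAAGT), singled out after its values were seen, was well above background on 10 of 12 control arrays and 1 of 12 ketoprofen arrays (adjusted p = 0.0506). It was at least 3.3-fold brighter in CTRL_14d than in KET_14d and at least 2.59-fold brighter in CTRL_60d than in KET_60d, and with normexp its average difference was -0.64 (adjusted p = 0.596). Among probes with higher values, ALL2_C3561_S had an average log2 difference of 0.69 ± 0.15 (adjusted p = 0.484), with 0.53, 0.81 and 0.74 at the 3 times. ALL2_REP_C92850_N (adjusted p = 0.484) was well above background on 2 of 12 control arrays and 7 of 12 ketoprofen arrays, and with normexp its average difference was 0.10. In all, 2280 probes passed an unadjusted p under 0.05.

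**Figure D2:**
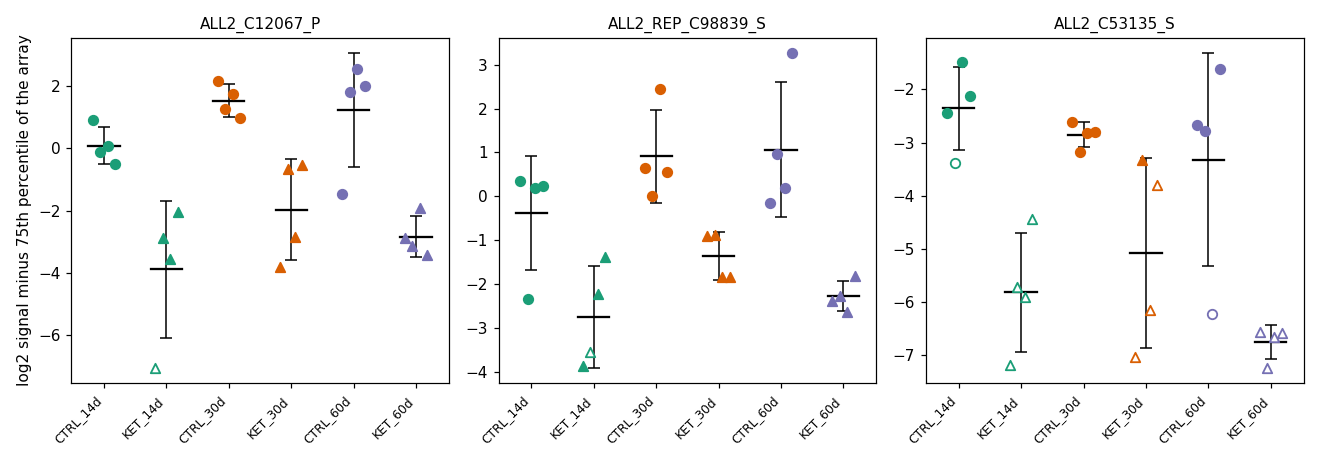
Log2 signal minus the array's 75th percentile (vertical axis) in each pool of the 6 groups for the 3 probes of smallest p in the average over times; circles are controls, triangles ketoprofen, open symbols arrays on which the probe was not well above background, and bars the mean ± SD (n = 4). For ALL2_C12067_P the group means are 0.08, 1.53 and 1.23 in controls and -3.89, -1.97 and -2.85 with ketoprofen.

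Whether the effect of ketoprofen differed between times was tested with limma's F-test of the interaction. No probe passed, the lowest adjusted p was 0.298, and 1873 probes passed an unadjusted p under 0.05. ALL2_REP_C17306_P, at least 29.7-fold brighter with ketoprofen at 30 days, had log2 differences of -1.46 at 14 days and -3.79 at 60 days, each with a standard error of 1.24. It was well above background on no CTRL_30d array but on all CTRL_14d and CTRL_60d arrays. In KET_14d and in KET_60d it was so on 2 of 4 arrays. ALL2_S82457_N was at least 3.49-fold brighter in CTRL_14d than in KET_14d, and was well above background on 3 of 4 CTRL_30d and 1 of 4 KET_30d arrays, and on 1 of 4 CTRL_60d and 4 of 4 KET_60d arrays. ALL2_C7893_P was at least 1.77-fold brighter in KET_30d than in CTRL_30d and at least 2.44-fold brighter in CTRL_60d than in KET_60d, with no CTRL_14d array and 1 KET_14d array well above background. Each of these had an adjusted p of 0.298, and ALL2_C7893_P was called without KET_30d array 1 (adjusted p = 0.0118). With normexp each had an adjusted p of 1, and the log2 effect differed by -4.25 between 60 and 30 days for ALL2_REP_C17306_P, by 1.03 between 60 and 14 days for ALL2_S82457_N and by -1.05 between 60 and 30 days for ALL2_C7893_P. Across 40402 probes, which are not independent replicates, the differences at 14 and 30 days correlated at r = -0.014 (exact permutation p = 0.833 over all splits of the pools within both times), those at 14 and 60 days at r = 0.04 (exact p = 0.544) and those at 30 and 60 days at r = 0.018 (exact p = 0.77). All 3 two-sided values were 0.833 after Benjamini-Hochberg adjustment.

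Over all probes, the distance between the ketoprofen and control means was compared with that between other splits of the same pools. The root mean square log2 difference was 0.758 at 14 days, 0.737 at 30 days and 0.801 at 60 days, against medians of 0.721, 0.781 and 0.797 over the 35 splits of each time. The exact one-sided permutation p was 0.143, 0.886 and 0.486, or 0.429, 0.886 and 0.729 after adjustment over the 3 times. Pools lay at a mean distance from their group mean of 0.943 ± 0.121 (SD, n = 4) in KET_14d and 0.797 ± 0.101 in CTRL_14d (exact permutation p = 0.114, two-sided). The distances were 0.913 ± 0.090 and 1.007 ± 0.047 at 30 days (exact p = 0.114) and 1.006 ± 0.098 and 0.971 ± 0.022 at 60 days (exact p = 0.543). The adjusted values were 0.171, 0.171 and 0.543. No exact p from 35 splits can fall under 1 in 35, so a difference at 1 time alone could not pass after adjustment. The distance between ketoprofen and control means summed over the 3 times has 42875 combined splits and is free of this limit. Of these, 24322 gave a sum as large as the real one (exact one-sided permutation p = 0.567).

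The controls alone were compared over time, as a view of change without the drug. Slide is partly mixed with time here. Slide 3 held 3 CTRL_60d arrays and no CTRL_14d or CTRL_30d array, so contrasts with 60 days partly compare slides. No probe passed limma's F-test over CTRL_14d, CTRL_30d and CTRL_60d, with a lowest adjusted p of 0.0832 and 3795 probes at an unadjusted p under 0.05. That count moved with the processing: it was 6980 with normexp, 5774 with array weights, 2478 without CTRL_14d array 4 and, chosen after seeing the data, 1815 with array brightness as a covariate. ALL2_REP_C23332_P and ALL2_REP_C14140_P were well above background on 3 of 4 CTRL_14d arrays and on no array of the other 5 groups, and were at least 2.98-fold and 2.99-fold brighter in CTRL_14d than in CTRL_60d (both adjusted p = 0.0832). ALL2_REP_C24986_P had its highest control mean in CTRL_30d, at -0.74 ± 0.82 (SD, n = 4), against -4.79 ± 2.33 in CTRL_60d, and was at least 8.22-fold brighter in CTRL_30d than in CTRL_14d (adjusted p = 0.205). With normexp these 3 differences were estimated at 1.73-fold, 1.69-fold and 1.8-fold, under the bounds from the processed signal (each adjusted p = 0.273). In the pairwise contrasts 1 probe was called: ALL2_REP_C45619_S was well above background on 4 of 4 CTRL_60d arrays and on no CTRL_30d array, at least 1.74-fold brighter (adjusted p = 0.0462), and 1.35-fold with normexp. In the F-test that probe had an adjusted p of 0.0832, and of 0.0151 without KET_14d array 1. The 30-to-14-day and 60-to-14-day contrasts called 0 probes, with 4741 and 3879 at an unadjusted p under 0.05. The CTRL_14d arrays were dimmer, with a 75th percentile signal of 113 ± 31.2 (SD, n = 4), than those of CTRL_30d at 222 ± 56.0 and CTRL_60d at 199 ± 79.3. Within slides, the contrast of 30 with 14 days called 2 probes on slide 1 and 1 on slide 2, from 2 arrays per group. On slide 2, with 1 CTRL_60d array assumed to vary like the others, that of 60 with 14 days called 3 and that of 60 with 30 days called 4.

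For 279 probe sequences printed at more than 1 place and well above background on all arrays, the median SD between copies on the same array was 0.085 log2 units. The median SD between the arrays of 1 group was 0.46 for the same sequences, which holds differences in labelling and hybridization as well as those between pools. Over all tested probes the median SD between arrays of 1 group was 0.70 log2 units. For a probe of median error the 95% interval of a ketoprofen difference at 1 time reached 2.02-fold either way, and that of the average over times 1.5-fold. Of the tested probes, 5911, or 14.5%, ranged over at least 64-fold between the lowest and the highest of the 24 pools, and 5169 of these were not well above background on at least 1 array.

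**Figure D3:**
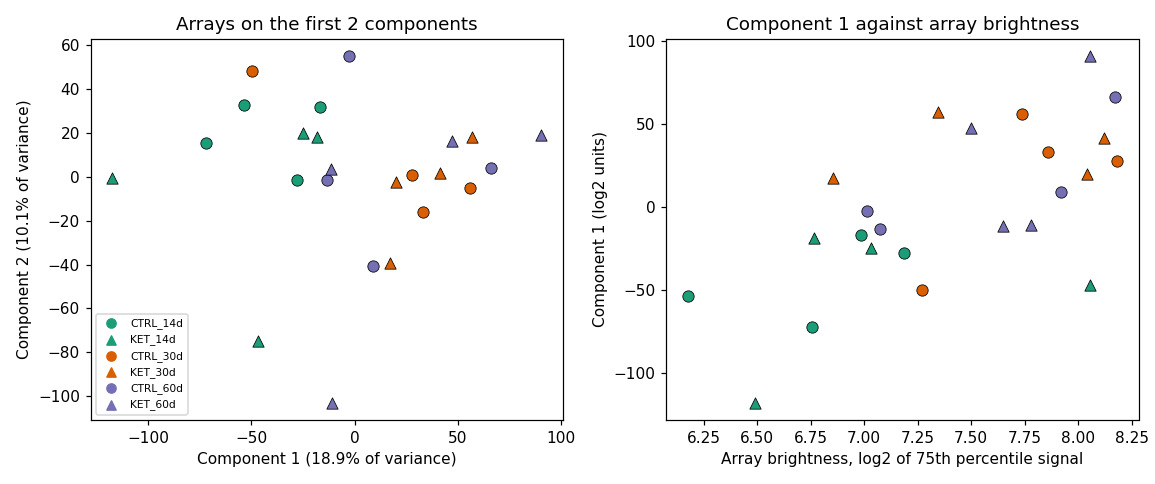
Left, the 24 arrays on the first and second principal components of the 24398 probes well above background on all arrays, with the share of variance on each axis; right, the first component against array brightness (log2 of the 75th percentile signal). Colours are times, circles controls and triangles ketoprofen; the first component holds 18.9% of the variance and correlates with brightness at r = 0.66.

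The first principal component held 18.9% of the variance and followed array brightness, with r = 0.66 (permutation p = 0.00045 from 100000 permutations) and rho = 0.67 (permutation p = 0.00055) over the 24 arrays, and r = 0.55 without the 2 arrays farthest from the median brightness. Within slides 1, 2 and 3 the correlation was 0.80, 0.74 and 0.82 over 8 arrays each, and after subtracting slide means it was 0.78 (permutation p = 2e-05). The component also went with time: every 14-day array had a negative score, against a minority of the later arrays. KET_14d array 1 was bright, with a 75th percentile signal of 265.5, and scored -46.98. These permutations mixed the times, and after subtracting group means r was 0.46 (permutation p = 0.024). Values with means subtracted were permuted as if all 24 were free. The permutation p after subtracting slide means or group means is therefore too low.

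Sets of probes varied together from pool to pool. Among the 5876 probes with at least a 64-fold range and no missing value, average-linkage clustering at a correlation of 0.8 gave 28 sets of 10 or more probes, 701 probes in all. The first 3 sets held 150, 108 and 58 probes. The mean of the first set ranged from -2.82 in KET_14d array 2 to 3.60 in KET_60d array 2. That of the second ranged from -5.64 in CTRL_60d array 1 to 2.79 in KET_30d array 4, and that of the third from -4.73 in CTRL_60d array 2 to 3.26 in CTRL_30d array 2. The exact two-sided permutation p of the 9 comparisons of ketoprofen with control pools, 3 sets at 3 times with n = 4, ranged from 0.171 to 0.943, or from 0.823 to 0.943 after Benjamini-Hochberg adjustment. With n = 4 such a p cannot fall under 1 in 35, so a lone difference could not pass after adjustment.

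**Figure D4:**
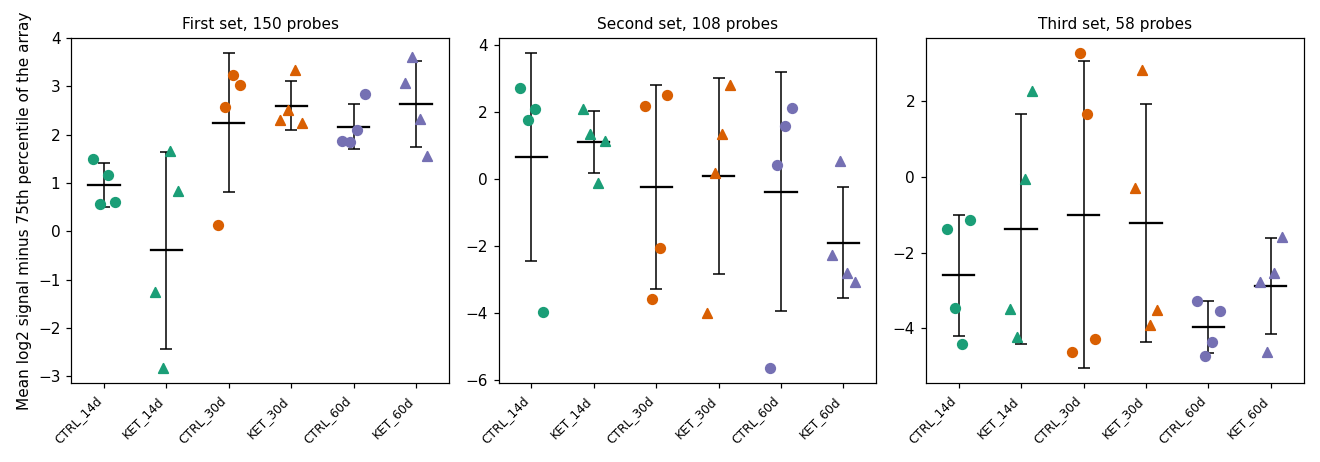
Mean log2 signal minus the array's 75th percentile (vertical axis) of the 3 sets of probes that varied together, per pool in each of the 6 groups; circles are controls, triangles ketoprofen, and bars the mean ± SD (n = 4). Pools of 1 group lie far apart, as in CTRL_14d for the second set, from -3.97 to 2.70.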

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

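Of the tests below, those of slide, of single arrays, of gain and of the 6 groups as explanations were chosen only after the result was seen.

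In 140 groups of 4 values, 9 held a value far from the other 3 by Dixon's test, where chance gives about 1 in 20. The mean correlation of CTRL_30d array 1 with its group was 0.893, against 0.913 to 0.915 for the other 3. The spike-in signal of KET_14d array 4 was 10.6 log2 units, against 11.1 to 11.2. ALL2_REP_C16136_P was at -4.87 in CTRL_14d array 3, ALL2_REP_C98839_S at -2.33 in CTRL_14d array 2 and ALL2_REP_C17306_P at -3.50 in CTRL_14d array 4, each below the other pools. ALL2_C53135_S was at -7.23 in KET_60d array 2, where no pool of the group was well above background. ALL2_C7893_P was at -5.83 in KET_14d array 4, below the other pools, and at -5.91 in KET_60d array 2, above them. The second set of probes that varied together had a mean of -3.97 in CTRL_14d array 4, against 1.75 to 2.70 in the other 3.

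The called probe, ALL2_C12067_P, was lower with ketoprofen. Slide as the whole cause is argued against by a log2 difference of -4.05 ± 0.53 (SE) with slide as a block. On leaving out 1 array the smallest difference was -3.50, and the call itself ended in 14 of 24 such fits. The size of that difference cannot decide on a single array as the cause, since each array has a small share in the average. At each time all ketoprofen pools lay below all control pools, so the direction did not rest on 1 array. Membership in a wider set of transcripts that fell together stayed open: 27 probes whose deviations from group means correlated over 0.7 with its own had a median average difference of -0.31, and a share of 0.11 of 1000 splits within times gave one as low. Another 28 probes had deviations that correlated under -0.7 with its own, so the 27 may not be a set. Chance was not excluded for the count of 1 called probe, since 9 of 100 splits within times, the real one included, called as many, and the highest other split called 2. An effect of the drug may be a candidate explanation, and it cannot be told apart from an effect of the tank, since the labels do not link pools to aquaria.

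The first principal component followed array brightness at r = 0.66. Gain of the whole array as the only source of brightness is argued against by the spike-in probes. Their mean log2 signal had a slope of 0.18 on log2 brightness (bootstrap 95% interval -0.03 to 0.41), where gain predicts a slope near 1. A part from gain stayed open, and the spike-in signal was not compared with the component itself. Slide is argued against by the lowest correlation within a slide, 0.74. The 6 groups stayed open, with r = 0.46 after subtracting group means (permutation p = 0.024, too low since the subtracted means leave fewer free values). The amount and quality of the RNA on each array were not tested.

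Other splits of the pools did not exclude chance for any count. At 14 days 3 of 35 splits, the real one included, gave as many probes at an unadjusted p under 0.05 as the real 2411, and the highest other gave 2597. At 30 days it was 33 of 35, with 1346 in the real split and 2909 in the highest other, and at 60 days 19 of 35, with 2270 and 4464. The 60-day split with 4464 put KET_60d arrays 1 and 2 and CTRL_60d arrays 3 and 4, all on slide 3, against the other 4, of which 3 were on slide 2. With slide as a block the real 60-day count was 2262, with 0 called by limma. Another 60-day split called 18 probes at an adjusted p under 0.05, against 0 in the real split. This may point to a structure of the samples other than the drug. The split is the highest of 35, and whether its count exceeds chance was not tested. For the interaction 46 of 100 splits gave as many as 1873, with a highest other of 3597. For control time 7 of 100 splits of the 12 control arrays gave as many as 3795, with a highest other of 5797.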

How the results depend on the processing

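The alternatives within slides and scan days, with array brightness as a covariate and without 3 arrays were chosen after seeing the data.

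On leaving out 1 array in turn, the count of called probes ranged from 0 to 5 at 14 days, 0 to 1 at 30 days, 0 to 2 at 60 days, 0 to 5 on average over the times, 0 to 1 for the interaction and 0 to 3 for control time. The highest counts came without KET_14d array 3 at 14 days, CTRL_60d array 3 on average and CTRL_14d array 3 for control time. At 14 days 1 probe was called after quantile normalization, in the series matrix and with array weights (ALL2_C68606_P each time), and 1 from the 8 arrays of that time alone (ALL2_REP_C14824_P). On average over the times median centring called 3 probes, ALL2_C12067_P, ALL2_C53135_S and ALL2_REP_C98839_S. Among the probes well above background on all arrays, which leave out ALL2_C12067_P, limma called 0, with 1283 at an unadjusted p under 0.05. Without KET_14d arrays 1 and 2 and KET_60d array 3 it called 0 on average, with 2156 unadjusted, and 1 for control time. Without the filter 1 probe was called for the interaction and 15 for control time. The replicate number as a block gave 0 calls on average over the times, with 2151 unadjusted, and changed no other ketoprofen count of called probes. Control time has no value with this block, which is nested in time. The numbers do not pair the pools: deviations of the 12 same-numbered pairs correlated between -0.133 and 0.096, and 1 of 12 ketoprofen arrays correlated best with the control of its number.

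With lone arrays assumed to vary like the others, the 14-day contrast called 1 probe within slide 1, 30 within slide 2 (1 ketoprofen array against 2) and 1 within scan day 1. The 30-day contrast called 2 within slide 1, 1 within scan day 1 and 2 within scan day 2, and the 60-day contrast 3 within slide 2 and 1 within scan day 2. Within slide 3 the 60-day contrast called 0 by limma, with 3363 at an unadjusted p under 0.05, and within scan day 2 the 14-day contrast called 0, with 1867. Slide 1 and scan day 1 hold the same arrays, so the values within them are not separate checks. All 60-day arrays were scanned on day 2. Within scan day 2 the 60-day contrast therefore compared the same arrays as the main one, with another estimate of spread. Slide or scan date as a block changed no count of called probes. Except for the probe left out by the filter, the cause of these changes was not tested. No named probe changed sign under any alternative that gave it a value. The median log2 difference of all probes between control 30 and 14 days was -0.11, and 0.01 after quantile normalization and -0.25 with normexp. At 14 days 1751 probes were at least 2-fold higher and 4112 lower with ketoprofen, and 2926 and 3421 after quantile normalization. The alternatives on gene lists were not run, since no list was applied. Signal over background limits the dim probes. Normexp brought the 14-day count at an unadjusted p under 0.05 to 784 from 2411, that of the average to 1345 from 2280 and that of the interaction to 1062 from 1873. The count of control time rose instead, to 6980 from 3795, whereas with array brightness as a covariate it was 1815. The rise is therefore not read as more change with time. Without the filter the 14-day count was 4043.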

Other observations

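The tests of array brightness and of ketoprofen for the sets of probes were chosen only after the result was seen.

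An S and an AS probe were present for 9289 contigs. What the suffixes S and AS stand for is not stated in the files, and 31 pairs are exact reverse complements. The S probe alone was among the tested probes for 4367 contigs, the AS probe alone for 1263, both for 1810 and neither for 1849. Where both were tested, their levels over the 24 arrays correlated at a median r of 0.21, against 0.023 to 0.06 in 100 random re-pairings.

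For the sets of probes that varied together, independent spot noise is argued against, since the largest set after shuffling each probe over the arrays held 6 probes. Shared probe sequence stayed open: 20.3% of the probes of the 3 sets shared a stretch of 20 bases with another of their set. As the main source, array brightness is argued against for the second and the third set by correlations of -0.35 and 0.26 with the set mean. The upper 95% limits of the absolute r were 0.66 and 0.60, so a smaller part from brightness stayed open. For the first set brightness stayed open, where r was 0.49 (permutation p = 0.015, 0.045 after adjustment over the 3 sets), rho 0.58 (permutation p = 0.0036) and r 0.65 without the 2 arrays of farthest set mean. As the source of the full range, ketoprofen is argued against for the second and the third set, whose control pools spanned 99% and 100% of it. It stayed open for the first, at 48.4%. Whether ketoprofen shifts the mean of a set is a separate question that these shares cannot decide. Both readings of the first set were made more cautious after its values were seen: its share lies under the bound of 50% set for ketoprofen, but without a group difference (exact permutation p of 0.343 at 14 days, the smallest of the 3 times), and its r lies under the bound of 0.5 set against brightness, but rho does not.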
